A study of Mus musculus with 10 samples.

How the data were processed

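Gene expression was measured by RNA sequencing in 10 libraries of bone marrow B-cell progenitors, 5 sorted as GFP high and 5 sorted as GFP low. Per the labels, polyadenylated RNA was purified with a small-scale column kit and amplified with a template-switching kit for very small RNA amounts. The deposited table held whole-number read counts per gene, not normalized, for 55573 Ensembl genes. The submitters' processing notes name the genome build mm10 and the tools STAR, featureCounts and DESeq2, with no role, version or setting for any of them. Whether counting used strand, and how reads with several matches were treated, is not given in the sources used here. Counts of overlapping genes, antisense genes and near-identical paralogs are therefore uncertain, and this holds for immunoglobulin segments, histone, hemoglobin, Gbp, Gimap and ribosomal protein genes. Gene symbols and positions came from the GENCODE M21 annotation of the mouse genome build GRCm38, which is the build mm10, and 99.833% of the identifiers matched. The 93 unmatched identifiers held 4219 of 129994434 counts. All 37 mitochondrially encoded genes were listed at 0 in every library and could not be tested. Of all genes, 29150 were listed at 0 in every library.

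Each library was assigned to its group and replicate number by its title. No pair of libraries within a group agreed within sampling noise, since the lowest chi-square per gene between a pair was 7.33. Total counts per library ranged from 10640894 to 14858520. Counts of 0 entered the tests and the CPM values (counts scaled to library size) as 0. As a guide to reading them, a floor of 3 counts per library corresponds to 0.202 to 0.282 CPM. This floor covers counting error only and was not applied to the values.

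The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings on the 2 groups, libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit and glmQLFTest) compared GFP high with GFP low without covariates. P-values were adjusted by the Benjamini-Hochberg method over the 12772 genes tested, with a threshold of 0.05. Log2 fold changes are GFP high over GFP low, with their standard errors (SE). CPM values used TMM-scaled library sizes and are given as mean ± SD. The common biological coefficient of variation was 0.249. On simulated counts for the same 12772 genes and 10 libraries, the test recovered 23.9% of genes changed 1.5-fold, 64.2% of genes changed 2-fold and 90.9% of genes changed 4-fold. The simulation changed 67, 67 and 66 genes at these folds and drew libraries without pairs. Far more genes were called in the data, where the adjusted threshold is therefore less strict, so these shares may differ from recovery there. Of 125 calls in that simulation, 6 were false and 0 had the wrong sign.

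The design, the alternatives, the gene lists and the naming rule were fixed before the data were examined. The rule named the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold. These genes needed a mean CPM of at least 5, and at least 4 of the 5 libraries of each group had to lie beyond the median of the other group. Had fewer than 3 genes passed in a direction, those with the lowest p would have been added up to 5. Predicted genes, clones, pseudogenes, receptor segments and mitochondrially encoded genes were left out of this part. The rule also named the 2 tested members with the lowest p from each primary list and 1 from each other list, and it always named Pax5, Eln, Mki67, Cdkn1b, Kit, Cd44, Il7r and Myc. It gave 61 genes. Other genes named in the text were chosen after their values were seen.

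The 31 lists fixed with their members were S phase, G2 and mitosis, cell cycle restraint, stem and early progenitor, early B-cell identity, PAX5 activated, PAX5 repressed, IL7R-STAT5 response, ribosome biogenesis and MYC targets, and mature B cell as primary lists. The secondary lists were small pre-B cell, plasma cell, adhesion and niche, ABC transporters, apoptosis, p53 targets, Notch and T-lineage factors, TGF-beta response, interferon response, immediate early, hypoxia and glycolysis, and oxidative phosphorylation. Marker lists covered T cells, NK cells, neutrophils, monocytes and macrophages, erythroid cells, megakaryocytes and platelets, plasmacytoid dendritic cells, basophils and mast cells, and stroma and endothelium. Another 3 families were found by symbol, namely cytosolic ribosomal proteins, replication-dependent histones and mitochondrially encoded genes. The symbol patterns of the first of these families and of the histones were corrected after the data were seen, and the patterns as first written were an added alternative. Lists with at least 5 tested members were compared with all other tested genes by camera in limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. In simulation, 1 raised list of 30 genes, 15 of them raised, was called among 41 lists and 0 other lists were. Members were also counted with p-values adjusted over the list alone.

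The labels number the replicates 1 to 5 in both groups and do not say what a number stands for. Deviations from the group means correlated between same-numbered libraries over 8000 genes, with Pearson correlations of 0.574, 0.463, 0.575, 0.696 and 0.641 for numbers 1 to 5. All exceeded the limit of 0.1 set before the data were examined, so the numbers were taken to pair the libraries. The limit does not tell pairs from other libraries, since differently numbered libraries exceeded it too. For GFP high libraries 1 to 5 the highest such correlations were 0.175, 0.301, 0.334, 0.638 and 0.655. GFP high libraries 1 to 4 correlated best with the same-numbered GFP low library. GFP high library 5 correlated best with GFP low library 4, at 0.655. Fits with the replicate number as a block were made beside the unblocked ones, and blocked values are given where they changed a call or moved a count of calls by over 1.5 times.

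Alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, no low count filter, a filter of 10 CPM in 5 samples, the replicate block, 1 surrogate variable from sva 3.50.0, removal of immunoglobulin and T-cell receptor genes, stricter thresholds, and leaving out each library in turn. List tests were repeated with an estimated correlation. Fry tested each list against no change, which is another question than a difference from other genes. Fits to replicates 1 to 3, to replicates 4 and 5, and to all but both libraries numbered 3 were chosen after the data were seen. So was the block combined with an estimated correlation. Summed CPM values and library measures were compared with two-sided exact permutation tests. These tests regrouped all 10 libraries and did not keep the pairs together. A two-sided exact test within 5 pairs has too few arrangements to pass the threshold, so none is given. The exact p-values therefore do not test differences within pairs, for which only directions are given.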

Results

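RNA was sequenced from bone marrow B-cell progenitors of mice that carried PAX5-ELN, a fusion of the B-lineage transcription factor gene PAX5 with the elastin gene ELN known from B-cell acute lymphoblastic leukemia, together with a GFP-tagged histone H2B. The tagged histone is diluted as cells divide, so GFP level separates cells by how much they have divided since labelling. The labels give doxycycline as the treatment, 35 days as the time, quiescent as the state of the 5 GFP high libraries and proliferating as the state of the 5 GFP low libraries. Total counts were 11347097 to 13838769 in GFP high and 10640894 to 14858520 in GFP low, and did not differ past the threshold (two-sided exact permutation test, p = 0.365, n = 5 and 5). The labels do not say that libraries came from separate animals, so p-values measure only the spread between these samples. Y-linked genes had 0 counts in both libraries numbered 3 and 293 to 2649 in the other libraries. This argues against replicate 3 being a technical repeat of the others. How far the spread among the other replicates is technical is not known.

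The mouse genes corresponding to the fusion partners were examined first, although it is not known whether reads of the transgene were assigned to them. Pax5 (ENSMUSG00000014030, mm10 chromosome 4, 44524757 to 44710487) had 5867, 4425, 5732, 4487 and 3549 counts in GFP high libraries 1 to 5 and 5055, 4676, 3129, 3548 and 4226 in GFP low libraries 1 to 5. Its mean was 374 ± 47.1 CPM in GFP high and 312 ± 34.4 CPM in GFP low (SD, n = 5 each), a log2 fold change of 0.26 ± 0.10 (SE) that did not pass the test by edgeR (Benjamini-Hochberg adjusted p = 0.0812). With the replicate block it passed (log2 fold change 0.26, adjusted p = 0.00352). It also passed without GFP high library 5 (0.34, adjusted p = 0.0192), without GFP low library 1 (0.32, adjusted p = 0.0454) and in replicates 1 to 3 alone (0.31, adjusted p = 0.0365), but not in replicates 4 and 5 alone (0.20, adjusted p = 0.126). Eln (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323) was near the limit of detection, with 16, 16, 16, 10 and 14 counts in GFP high and 12, 20, 6, 18 and 24 in GFP low. Its log2 fold change was -0.07 ± 0.37 (adjusted p = 0.916), and the sign turned without GFP high library 4 (0.05) and without GFP low library 2 (0.01), 4 (0.01) or 5 (0.08). With single libraries left out the lowest value was -0.23, without GFP low library 3. It was 0.37 in replicates 1 to 3 alone and -0.63 in replicates 4 and 5 alone.

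The comparison of GFP high with GFP low asked which genes differ between B-cell progenitors labelled quiescent and those labelled proliferating. Genes of DNA replication and mitosis fell in GFP high: all 36 tested genes of G2 and mitosis and 32 of 35 S phase genes were lower, among them the cyclin genes Ccne2 (log2 fold change -1.65 ± 0.11, 43.0 ± 3.37 against 135 ± 20.97 CPM) and Ccnb2 (-1.45 ± 0.10, 120 ± 11.4 against 328 ± 36.9 CPM). Genes of oxidative phosphorylation and cytosolic ribosomal proteins also fell, with 25 of 26 and 69 of 83 members lower. As lists, neither passed with an estimated correlation (adjusted p = 0.206 and adjusted p = 0.309). The IL-7 receptor gene Il7r (0.96 ± 0.13, 1300 ± 151 against 670 ± 123 CPM) and the IL-2 receptor alpha chain gene Il2ra (2.23 ± 0.34, 251 ± 126 against 53.4 ± 19.1 CPM) rose. Csf1r, the receptor of a monocyte growth factor, rose from 5.92 ± 1.81 to 26.1 ± 4.24 CPM (2.14 ± 0.22), while the B-lineage genes Ebf1 and Cd79a rose as well (SE and SD, n = 5 each).

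Of 12772 genes tested, 1538 were higher and 1973 lower in GFP high (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 389 and 364 differed at least 2-fold. The groups did not overlap for 20.5% of tested genes, against 0.794% by chance. With the replicate block 2645 genes were higher and 2688 lower. This kept 3486 of the 3511 calls. In replicates 1 to 3 alone 1409 were higher and 1629 lower, and in replicates 4 and 5 alone 1332 and 1432. Without both libraries numbered 3 there were 926 higher and 1367 lower.

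In the S phase list 0 genes rose, 32 fell and 3 did not pass, and 33 fell adjusted over the list alone. The median log2 fold change was -0.95 (camera adjusted p = 5.84e-41, and adjusted p = 0.0384 with an estimated correlation). The list did not pass with the replicate block and an estimated correlation (adjusted p = 0.0906). Within replicates 1 to 3 the median was -0.91 and within replicates 4 and 5 it was -0.93. Chaf1b, a subunit of the chromatin assembly factor that deposits histones at replication forks, fell by 1.18 ± 0.09 on the log2 scale. The 3 members that did not pass, named after their values were seen, were Fen1 (-0.50, adjusted p = 0.1199), Cdt1 (-0.31, adjusted p = 0.3197) and Ung (-0.13, adjusted p = 0.643). Of these, Cdt1 passed with the replicate block (-0.32, adjusted p = 0.0123). In the G2 and mitosis list 36 fell, also adjusted over the list alone, with a median of -1.16 (camera adjusted p = 2.12e-55, and adjusted p = 0.0384 with an estimated correlation), -1.11 in replicates 1 to 3 and -1.18 in replicates 4 and 5. The spindle gene Nusap1 had 150 ± 10.6 CPM in GFP high and 336 ± 21.9 CPM in GFP low. The proliferation marker Mki67 (chromosome 7, 135689784 to 135716361) fell by 1.19 ± 0.27 (adjusted p = 0.00664) and still had 178 ± 60.7 CPM in GFP high against 406 ± 136 in GFP low.

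**Figure D1:**
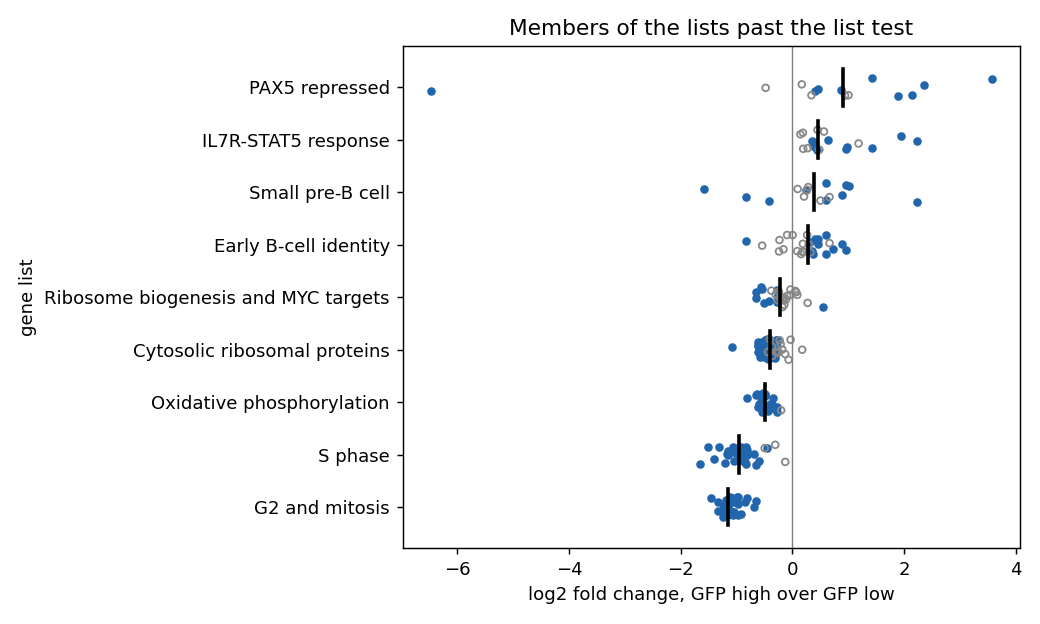
Log2 fold change (GFP high over GFP low) of each tested member of the 9 lists past the list test, with filled points for genes past an adjusted p of 0.05, open points for the others and a black bar at the list median. Medians ran from -1.16 for G2 and mitosis to 0.91 for genes repressed by PAX5, where Jchain lies apart at -6.48. Of the 9 lists, S phase and G2 and mitosis also passed with an estimated correlation, and the other 7 did not.

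Of 69 replication-dependent histone genes 34 were tested. Of these 0 were higher, 6 lower and 28 not past the threshold, with 0 and 4 adjusted over the list alone. In the fit with the replicate block 1 was higher and 11 lower. Their list test did not pass (median -0.55, camera adjusted p = 0.0930). It passed with the replicate block (adjusted p = 0.0322), but not with that and an estimated correlation (adjusted p = 0.372). It also passed without GFP high library 1 (adjusted p = 0.0122), GFP high library 2 (adjusted p = 0.00578), GFP low library 4 (adjusted p = 0.0184) or GFP low library 5 (adjusted p = 0.0365). It did not pass in the other 6 fits with a library left out. The highest adjusted p was 0.301 without GFP high library 4 (median -0.37). The median nearest 0 was -0.23 without GFP low library 1. Hist1h2ab fell by 1.56 ± 0.28. The libraries were made from polyadenylated RNA, and the tested histone genes had low counts (median 2.69 CPM in GFP high and 4.28 CPM in GFP low). These values therefore cover only polyadenylated histone transcripts and do not measure histone RNA as a whole. In the cell cycle restraint list 6 genes rose, 2 fell and 19 did not pass, with the same counts adjusted over the list alone (median 0.31, camera adjusted p = 0.209). In the fit with the replicate block 12 rose and 6 fell. The list passed with the block (adjusted p = 0.0145) and in replicates 4 and 5 alone (adjusted p = 2.41e-05), but not in replicates 1 to 3 alone (median 0.20, adjusted p = 0.387) or with the block and an estimated correlation (adjusted p = 0.372). Its median was 0.21 without GFP high library 4. Foxo1, a transcription factor that restrains growth and drives early B-cell genes, rose by 0.60 ± 0.08 to 768 ± 49.3 CPM. The members that fell were inhibitors of cyclin-dependent kinases, Cdkn2d (-0.59 ± 0.10) and, named after its values were seen, Cdkn2c (-0.44 ± 0.10, adjusted p = 0.00713). Cdkn1b, which encodes the inhibitor p27, had a log2 fold change of 0.31 ± 0.19 (adjusted p = 0.247, with the replicate block adjusted p = 0.0382).

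In the early B-cell identity list 11 genes rose, 1 fell and 16 did not pass, with 16 and 1 adjusted over the list alone. Counts with the replicate block were 19 and 2. The median was 0.28 (camera adjusted p = 0.000846, and adjusted p = 0.0553 with an estimated correlation). Sox4 rose by 0.72 ± 0.09 and Igll1, which encodes a part of the surrogate light chain, rose by 0.46 ± 0.06 to 3413 ± 204 CPM. Ebf1 (0.60 ± 0.09, adjusted p = 0.000414) and the recombinase gene Rag1 (0.88 ± 0.19, adjusted p = 0.004002) rose, and the member that fell was Ikzf3 (-0.83 ± 0.29, adjusted p = 0.04899). Ikzf3 did not pass with the replicate block (-0.81, adjusted p = 0.0606). These 3 genes were named after their values were seen. Among genes activated by PAX5, 5 rose, 1 fell and 9 did not pass, with the same counts adjusted over the list alone (median 0.12, camera adjusted p = 0.144). The list passed with the replicate block (adjusted p = 0.0188) and in replicates 1 to 3 alone (median 0.21, adjusted p = 0.0378). It did not pass in replicates 4 and 5 alone (median 0.09, adjusted p = 0.0511) or with the block and an estimated correlation (adjusted p = 0.313). The median rose to 0.20 without GFP low library 1. They included Bank1, a B-cell signalling adaptor (1.21 ± 0.13), and Cd79a, a chain of the B-cell receptor complex (0.40 ± 0.10).

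Among genes repressed by PAX5, 8 rose, 1 fell and 5 did not pass, with 9 and 1 adjusted over the list alone (median 0.91, camera adjusted p = 0.00495, and adjusted p = 0.206 with an estimated correlation). Csf1r (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149) had the lowest adjusted p of the members that rose (3.53e-05). Lmo2, a cofactor of early hematopoietic transcription, rose by 0.88 ± 0.11, and Id2, an inhibitor of E proteins, rose by 1.43 ± 0.37. Cd33 (1.89 ± 0.41, adjusted p = 0.00445) and Flt3, a receptor of early lymphoid progenitors (2.36 ± 0.70, adjusted p = 0.0244, 4.88 against 0.933 CPM), rose too and were named after their values were seen. Csf1r is also in the monocyte and macrophage marker list, and whether other cells contributed to these rises was not tested. The member that fell was Jchain (ENSMUSG00000067149, chromosome 5, 88519809 to 88527891), which encodes the joining chain of secreted antibodies. It had 2 to 16 counts in GFP high libraries and 394 to 1204 in GFP low libraries (log2 fold change -6.48 ± 0.44, adjusted p = 6.18e-06).

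In the IL7R-STAT5 response list 10 genes rose, 0 fell and 8 did not pass, with the same counts adjusted over the list alone. Counts with the replicate block were 16 and 0. The median was 0.46 (camera adjusted p = 1.38e-05, adjusted p = 0.0840 with an estimated correlation, and adjusted p = 0.0333 with that and the block). It was 0.50 in replicates 1 to 3 and 0.65 in replicates 4 and 5. Besides Il7r (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176) and Il2ra (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193), the STAT5 target Cish (1.43 ± 0.39, adjusted p = 0.0157), the cyclin gene Ccnd2 (1.95 ± 0.36, adjusted p = 0.00189) and the survival gene Bcl2 (0.97 ± 0.18, adjusted p = 0.00196) rose, the last 3 named after their values were seen. Myc had a log2 fold change of 0.27 ± 0.21 (adjusted p = 0.359) that passed with the replicate block (adjusted p = 0.00551) and in replicates 4 and 5 alone (0.38, adjusted p = 0.00724), but not in replicates 1 to 3 alone (0.18, adjusted p = 0.631). Leaving out 1 library moved Myc to between 0.15 (without GFP low library 2) and 0.41 (without GFP high library 2). The small pre-B cell list had 7 genes higher, 3 lower and 6 not past the threshold, with 9 and 3 adjusted over the list alone. Counts with the replicate block were 11 and 2. The median was 0.39 (camera adjusted p = 0.00630, and adjusted p = 0.0708 with an estimated correlation). Cd2 rose by 1.02 ± 0.10, while the kappa light chain constant gene Igkc fell by 1.58 ± 0.21 and Spib by 0.42 ± 0.13, both named after their values were seen. Il7r, Il2ra and Foxo1 are members of this list as well, and Ikzf3 is the third that fell.

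Of 32 members of the stem and early progenitor list, 15 were tested. The list had 4 genes higher, 1 lower and 10 not past the threshold, with 5 and 1 adjusted over the list alone (median 0.35, camera adjusted p = 0.148). It passed with the replicate block (adjusted p = 0.0322), but not with that and an estimated correlation (adjusted p = 0.293). Its median was 0.19 without GFP low library 1. Kit, the receptor of stem cell factor (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722), had 178 ± 94.2 CPM in GFP high and 78.8 ± 43.5 CPM in GFP low. Its log2 fold change of 1.17 ± 0.42 was positive in 5 of 5 pairs and did not pass without the block (adjusted p = 0.0587). It passed with the replicate block (adjusted p = 3.43e-07), within replicates 1 to 3 (1.17, adjusted p = 0.0197), within replicates 4 and 5 (1.17, adjusted p = 2.91e-05), and without GFP high library 2 (1.33, adjusted p = 0.0463), GFP high library 3 (1.34, adjusted p = 0.0399) or GFP low library 5 (1.44, adjusted p = 0.0305). The adhesion receptor gene Cd44 fell by 1.22 ± 0.12, from 66.3 ± 7.998 to 28.4 ± 3.60 CPM. In the adhesion and niche list, which also holds Cd44, 7 genes rose, 4 fell and 6 did not pass, with the same counts adjusted over the list alone (median 0.29, camera adjusted p = 0.5003). In the fit with the replicate block 11 rose and 4 fell. The list passed with the block (adjusted p = 0.0322) and in replicates 4 and 5 alone (adjusted p = 0.00971), but not in replicates 1 to 3 alone (median 0.23, adjusted p = 0.314) or with the block and an estimated correlation (adjusted p = 0.313). The integrin genes Itga5 (1.004 ± 0.16) and Itga4 (0.46 ± 0.08) rose and Itga6 (-1.59 ± 0.20) fell, all named after their values were seen.

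**Figure D2:**
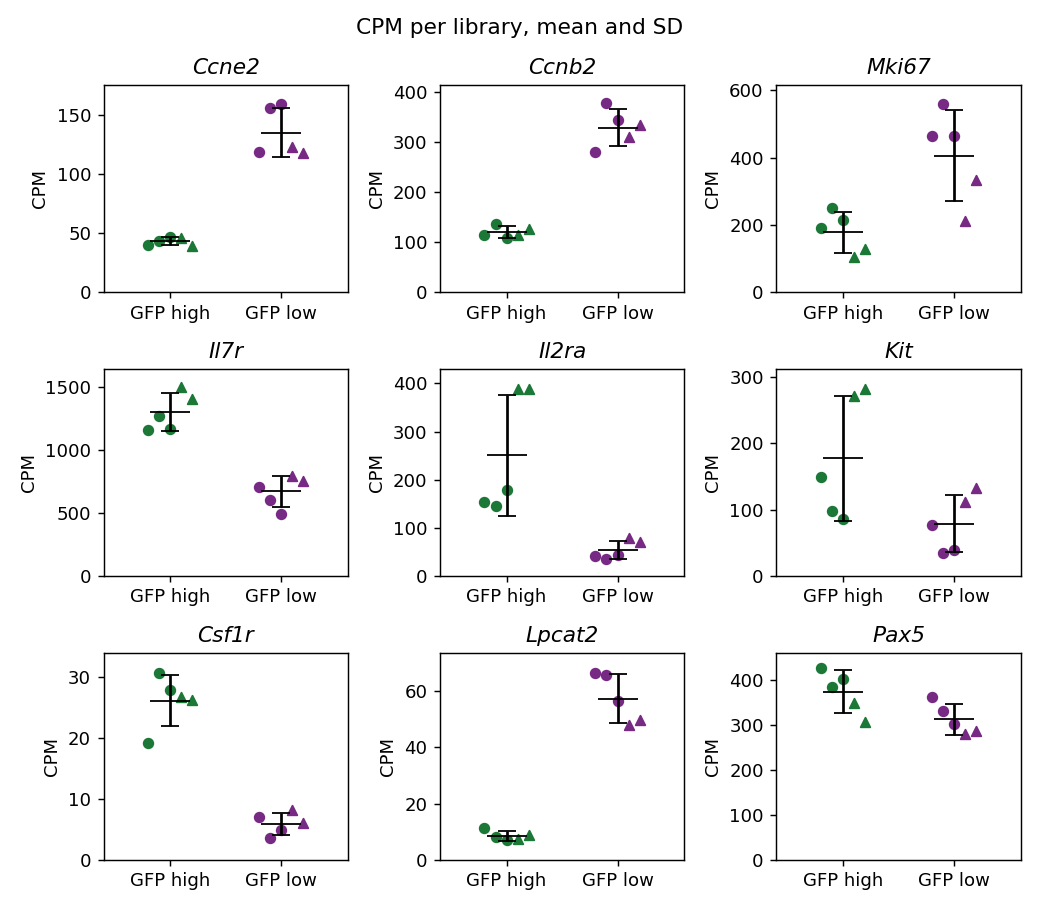
CPM per library for 9 genes in GFP high (green) and GFP low (purple), with circles for replicates 1 to 3, triangles for replicates 4 and 5, and bars for the mean ± SD of 5 libraries. Ccnb2 averaged 120 CPM in GFP high and 328 CPM in GFP low, and the Kit and Il2ra values of replicates 4 and 5 lie above those of replicates 1 to 3 within each group.

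Ribosome biogenesis and MYC target genes had 1 gene higher, 9 lower and 17 not past the threshold, with 1 and 10 adjusted over the list alone. Counts with the replicate block were 2 and 13. The median was -0.22 (camera adjusted p = 0.0153, and adjusted p = 0.376 with an estimated correlation). The nucleolar genes Npm1 and Fbl both fell, by 0.65 ± 0.07 and 0.65 ± 0.11 on the log2 scale, and the gene that rose was Ppan (0.54 ± 0.13), named after its values were seen. Cytosolic ribosomal protein genes had 0 higher and 69 lower, with 0 and 73 adjusted over the list alone (median -0.41, camera adjusted p = 2.44e-17, and adjusted p = 0.309 with an estimated correlation). Rps27l fell by 1.08 ± 0.13. The exact tests of shares that follow did not keep the pairs together. As a share of all counts these genes made up 1.93% ± 0.168 in GFP high and 2.46% ± 0.121 in GFP low (SD, n = 5, two-sided exact permutation test, adjusted p = 0.0278 over 7 library measures). The share of protein-coding genes was lower as well (97.4% ± 0.0736 against 97.6% ± 0.0947, adjusted p = 0.0278), and that of the 10 most abundant genes was higher (4.39% ± 0.144 against 4.01% ± 0.143, adjusted p = 0.0370). In the oxidative phosphorylation list 0 rose, 25 fell and 1, Sdha, did not pass (-0.20, adjusted p = 0.122, with the replicate block adjusted p = 0.00863, named after its values were seen), and 26 fell adjusted over the list alone (median -0.49, camera adjusted p = 1.15e-12, and adjusted p = 0.206 with an estimated correlation). The ATP synthase gene Atp5b fell by 0.57 ± 0.07. The hypoxia and glycolysis list had 3 genes higher, 6 lower and 10 not past the threshold, with 4 and 6 adjusted over the list alone (median -0.17, camera adjusted p = 0.164, and a median of -0.27 without GFP low library 2). Lactate dehydrogenase Ldha fell by 0.75 ± 0.10.

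The largest rises among genes that met the naming rule were in Gng4, a G protein subunit (log2 fold change 3.20 ± 0.49, 80.7 ± 37.6 against 8.77 ± 6.20 CPM, chromosome 13, 13784059 to 13827896), and Myof, a membrane repair protein (3.04 ± 0.39, 69.2 ± 15.8 against 8.35 ± 5.63 CPM). Dlx1 (2.95), Ifitm1 (2.89), Ankrd63 (2.88), Dtx4 (2.86), the sphingosine-1-phosphate receptor gene S1pr3 (2.85) and the mucin gene Muc13 (2.75, 138 ± 45.8 against 20.4 ± 11.8 CPM) followed, with adjusted p from 0.000148 for Myof to 0.00545 for Ifitm1. The largest falls after Jchain were in Clic6 (-3.83 ± 0.64), Lpcat2, a lysophosphatidylcholine acyltransferase (-2.76 ± 0.16, 8.48 ± 1.78 against 57.4 ± 8.73 CPM, chromosome 8, 92855339 to 92919279), the argininosuccinate synthase gene Ass1 (-2.33 ± 0.20), Nt5dc2 (-2.19), Itm2a (-2.09), the tetraspanin gene Cd9 (-2.00) and the cytokine gene Il33 (-1.98). All 16 moved the same way in 5 of 5 pairs.

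The mature B cell list had 4 genes higher, 1 lower and 13 not past the threshold, with the same counts adjusted over the list alone and 6 and 2 with the replicate block (median 0.22, camera adjusted p = 0.154, without GFP high library 1 a median of 0.35 and adjusted p = 0.0353). Without GFP low library 5 the median was 0.36. Ccr7, a chemokine receptor, rose by 1.63 ± 0.16 and the MHC class II gene H2-Ab1 fell by 0.72 ± 0.09. The plasma cell list had 3 higher, 3 lower and 4 not past the threshold, with 4 and 3 adjusted over the list alone and 5 and 3 with the replicate block. Its median was 0.22 and its mean -0.42, and the direction of its test was down (camera adjusted p = 0.869). The ABC transporter list had 3 higher and 0 lower of 8 (median 0.45, camera adjusted p = 0.148), led by the cholesterol exporter gene Abcg1 (0.86 ± 0.21). The apoptosis list had 2 higher and 1 lower of 11 and with the replicate block 5 and 2 (median 0.16, camera adjusted p = 0.316), with a rise of the BH3-only gene Bmf (0.78 ± 0.11). Its median was 0.08 without GFP low library 1 and 0.26 without GFP low library 5. The p53 target list had 2 higher and 5 lower of 18 and with the replicate block 4 and 8 (median -0.12, camera adjusted p = 0.131, in replicates 1 to 3 adjusted p = 0.0150, in replicates 4 and 5 a median of -0.06 and adjusted p = 0.195). Without GFP high library 3 the median was -0.18. The member with the lowest p was Gtse1 (-1.26 ± 0.11), which is also a gene of the G2 phase. The unblocked counts of these last 3 lists were the same adjusted over the list alone.

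Among signalling lists, Notch and T-lineage factors had 2 genes higher and 1 lower of 7 (median 0.22, camera adjusted p = 0.517) and TGF-beta response genes 3 higher and 1 lower of 10 (median 0.39, camera adjusted p = 0.175), with the same counts adjusted over the list alone. The Notch median turned to -0.09 without GFP high library 2 and to -0.04 without GFP high library 3, and was 0.42 without GFP low library 2. With the replicate block the TGF-beta list had 5 higher and 1 lower. Id2 belongs to both, and the receptor gene Tgfbr2 rose by 0.58 ± 0.11. Interferon response genes had 6 higher and 1 lower of 20, with 8 and 2 adjusted over the list alone and 10 and 2 with the replicate block (median 0.38, camera adjusted p = 0.131, without GFP high library 1 a median of 0.24), and the one that fell was Ifi27l2a (-0.88 ± 0.17). Immediate early genes had 1 higher and 0 lower of 16, also adjusted over the list alone, and 12 and 0 with the replicate block (median 0.33, camera adjusted p = 0.144). This list passed with the replicate block (adjusted p = 2.16e-05), but not with that and an estimated correlation (adjusted p = 0.313). It also passed in replicates 4 and 5 alone (median 0.68, adjusted p = 2.92e-11) and without GFP low library 1 (median 0.61, adjusted p = 0.0355), but not in replicates 1 to 3 alone (median 0.22, adjusted p = 0.120). The median was lowest, at 0.21, without GFP low library 5. Its member that rose was Zfp36 (0.50 ± 0.14, adjusted p = 0.0165), which did not pass in replicates 1 to 3 alone (0.44, adjusted p = 0.1001).

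Single markers of other cell types went in both directions. Many members of some marker lists were not tested. Tested were 6 of 18 T-cell, 3 of 12 NK-cell, 3 of 16 neutrophil and 7 of 15 erythroid markers. In GFP high, Klrb1c, Zap70 and Car2 had 274, 17.2 and 607 CPM, far above their list medians of 1.69, 2.27 and 4.47 CPM. In GFP low they had 107, 42.7 and 918 CPM, against 2.19, 3.39 and 2.35 CPM. Their changes therefore do not stand for their lists. The mean log2 CPM of the monocyte and macrophage, erythroid and plasmacytoid dendritic cell lists was higher in GFP high in every pair. That of the T cell list was higher in pairs 1 to 3 and lower in pairs 4 and 5. T-cell markers had 0 higher and 2 lower of 6, with a median of 0.47, a mean of -0.07 and a test direction of down (camera adjusted p = 0.732, with a median of -0.53 in replicates 4 and 5), and Zap70 fell by 1.31 ± 0.21. Of 3 tested NK-cell markers, Klrb1c rose (1.36 ± 0.26, 274 ± 62.8 against 107 ± 43.4 CPM), and 2 were higher and 1 lower adjusted over the list alone and 1 and 1 with the replicate block. None of 3 neutrophil markers passed. S100a9 had 2.63 against 1.14 CPM (1.19 ± 0.49, adjusted p = 0.0922), which passed with the replicate block (adjusted p = 0.0375), without GFP low library 5 (adjusted p = 0.0445) and in replicates 1 to 3 (2.16, adjusted p = 0.0273), but not in replicates 4 and 5 (0.33, adjusted p = 0.720). Monocyte and macrophage markers had 2 higher and 1 lower of 12, with 3 and 1 adjusted over the list alone and 5 and 1 with the replicate block (median 0.38, camera adjusted p = 0.172, without GFP low library 1 a median of 0.25), led by Csf1r. Erythroid markers had 1 higher and 1 lower of 7, with 2 and 1 adjusted over the list alone and with the replicate block (median 0.93, camera adjusted p = 0.417, without GFP high library 3 a median of 0.49), and Car2 fell by 0.60 ± 0.15. Hemoglobin genes made up 0.0026% ± 0.0013 of counts in GFP high and 0.0012% ± 0.0005 in GFP low (SD, n = 5, exact permutation adjusted p = 0.0694), higher in GFP high in 5 of 5 pairs. Plasmacytoid dendritic cell markers had 3 higher and 0 lower of 7, also adjusted over the list alone (median 0.22, camera adjusted p = 0.154, without GFP low library 5 a median of 0.09). Siglech had 20 to 82 counts in GFP high and 0 to 4 in GFP low (adjusted p = 0.000230). None of 2 megakaryocyte and platelet markers, 1 basophil and mast cell marker or 3 markers of stroma and endothelium passed. These were the members tested from lists of 10, 9 and 12 genes. Gp9 had a log2 fold change of -0.49 ± 0.35, Hdc 0.25 ± 0.42 and Cxcl12 1.95 ± 1.16. Leaving out 1 library moved Gp9 to -0.30 (without GFP low library 5), Hdc to between -0.06 (without GFP high library 1) and 0.51 (without GFP low library 1), and Cxcl12 to 0.09 (without GFP high library 2).

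The first principal component of 8000 genes held 47.2% of the variance and separated GFP high (scores -23.0 to -18.0) from GFP low (15.8 to 27.4). The second held 28.9% and separated replicates 1 to 3 (-20.6 to -9.64) from replicates 4 and 5 (16.7 to 20.8) in both groups. A test of whether the difference between GFP high and GFP low differed between these sets called 1 gene by edgeR, Gm9531 (difference 3.65 on the log2 scale, adjusted p = 0.0104), named after its values were seen, with 574 genes at an unadjusted p under 0.05. With the replicate block it called 2, Gm9531 (adjusted p = 0.000758) and Rpl37a (difference 1.267, adjusted p = 0.00691), the latter also named after its values were seen. Transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were counted in both libraries of replicates 1, 2, 4 and 5 and in neither library of replicate 3. Their summed CPM was 59.3, 152, 130 and 230 in GFP high libraries 1, 2, 4 and 5 and 20.7, 34.8, 53.3 and 158 in GFP low libraries 1, 2, 4 and 5. None of the 4 passed without the block, and all passed with it, from Eif2s3y (log2 fold change 0.97, adjusted p = 0.00141) to Uty (2.05, adjusted p = 0.000454). All 10 libraries also held Xist, the X-inactivation transcript of female cells, at 13.2 to 78.7 CPM.

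**Figure D3:**
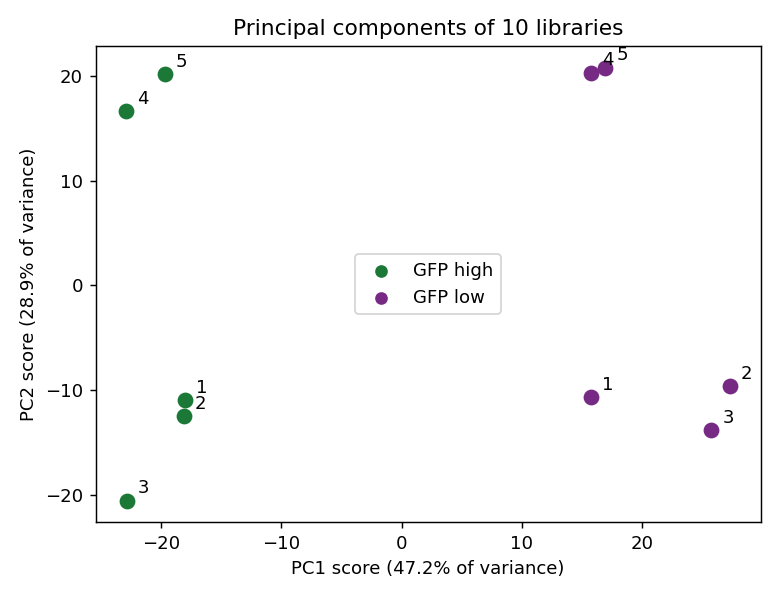
Scores of 10 libraries on the first and second principal components of log2 CPM over 8000 genes, numbered by replicate and colored by group. GFP high and GFP low separate along the first component (47.2% of variance), and replicates 4 and 5 lie above replicates 1 to 3 along the second (28.9%).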

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

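All tests of Y-linked transcripts, of the second principal component and of Jchain with kappa light chain transcripts were chosen after the result was seen, whereas the comparison with other splits of the libraries was fixed beforehand. Of 100 splits drawn from 126, 1, the real split, called as many as 3511 genes, and the highest other split called 72. Every other split mixes GFP high with GFP low libraries, which widens the spread within its groups and made few calls likely beforehand. The calls thus follow the sorted groups, but the comparison does not exclude chance. The highest of the other 12 splits that part all 5 pairs called 0 genes by edgeR, and the median over the other splits was 0. Where pairs are kept, 12 other splits are too few to exclude chance. The split with 72 calls parts 1 of the 5 pairs, whereas the real split parts all of them.

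In 342 tests of groups of 5 values for a library far from the others, 4 flagged one. Groups of CPM values were tested both as printed and on the log2 scale. Chance gives about 1 in 20, which is more than were flagged, so the 4 are listed without a claim beyond chance. Clic6 had 28.9 CPM in GFP low library 3, against 16.0 to 19.4 in the other libraries of its group. Cxcl12, a chemokine of bone marrow stroma, had 15.9 CPM in GFP high library 2, against 0 to 3.5 in the other GFP high libraries. Without that library its log2 fold change was 0.09 in place of 1.95, and neither passed the test. The mean log2 CPM of the monocyte and macrophage list was 3.3 in the same library, against 2.65 to 2.84 in the other GFP high libraries. The interferon response list stood at 4.63 in GFP low library 1, against 4.32 to 4.39 in the other GFP low libraries.

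Summed transcripts of 4 Y-linked genes were higher in GFP high in 4 of 4 pairs that held them, and each of the 4 genes passed with the replicate block, from Eif2s3y (log2 fold change 0.97, adjusted p = 0.00141) to Uty (2.05, adjusted p = 0.000454), and none without it. The share of cells from male animals may have differed between the sorted fractions, since in 4 of 4 pairs with Y-linked counts the sum was higher and Xist lower in GFP high. The Y-linked sums had ratios of 2.86, 4.37, 2.45 and 1.46, and Xist had 0.915, 0.888, 0.894 and 0.615. A shift in the share of cells would move the 4 genes alike: ratios ran from 2.35 to 10.1 in pair 1 and 2.89 to 7.89 in pair 2, but from 2.01 to 3.3 in pair 4 and 1.13 to 2.17 in pair 5, so this and a difference in Y-linked transcription cannot be told apart. A different sex mix as the cause of the calls is argued against, because 98.6% of 2293 genes called in the other 8 libraries had the same direction in pair 3, which held no Y-linked counts, compared with 75.1% of genes not called.

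The second component set replicates 1 to 3 apart from replicates 4 and 5, and the design names no biological difference between them, so none from the design was set against the explanations below. An early stress response that differed between the sets is a candidate explanation: the mean loading of 14 immediate early genes lay at percentile 0.01 of 10000 expression-matched random lists, the smallest they can give. The immediate early score was 6.53 to 6.59 in GFP high libraries 4 and 5 and 7.21 to 8.06 in the other GFP high libraries. The random lists were drawn gene by gene, whereas genes of this list vary together (estimated correlation 0.425), which can by itself make a loading extreme. Other lists also separated the sets. The histone score was 0.918 and 1.38 in GFP high libraries 4 and 5 and 1.91 to 2.55 in the other GFP high libraries. GC content bias as the whole cause is argued against by a Spearman rho across genes of 0.0463 between loading and GC content, genes not being independent replicates. What else separated the sets stays open.

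Jchain and kappa light chain transcripts were lower in GFP high. Plasma cells in the GFP low libraries may contribute, but of 9 other tested plasma cell genes 2 fell (Fkbp11 and Txndc5), 3 rose (Derl3, Sdc1 and Xbp1) and 4 did not pass, with 2 lower and 5 higher with the replicate block, which leaves this explanation open. Igha, chosen after its values were seen, had 834 and 1197 counts in GFP low libraries 3 and 5 and 0 to 19 in the other libraries, while Jchain was high in all 5 GFP low libraries. Summed kappa V segments had 162 ± 26.5 CPM in GFP high and 393 ± 50.3 in GFP low, lower in 5 of 5 pairs (two-sided exact permutation test, adjusted p = 0.0185 over 7 groups of segments), which is part of the same fall in kappa transcripts and does not account for Jchain. Ighm went the other way in 5 of 5 pairs, at 7246 ± 376 against 6260 ± 206 CPM (exact adjusted p = 0.0185). A general loss of immunoglobulin transcripts is thus argued against. Neither exact test kept the pairs together.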

How the results depend on the processing

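The fits to replicates 1 to 3, to replicates 4 and 5 and without both libraries numbered 3, the list patterns as first written, and the block with an estimated correlation were tests chosen after the data were seen. Genes named by the rule and past the threshold kept their direction and their call in 1084 recomputed values and lost it in 1, Zfp36 in replicates 1 to 3 (0.44, adjusted p = 0.1001). These values do not cover the stricter thresholds, under which single genes were not scored. Id2 (edgeR adjusted p = 0.0125), Zfp36 (0.0165) and Car2 (0.0111) would not pass at 0.01. Most named genes were picked for a low p or a large change in these same libraries, so few losses were likely beforehand. No called gene was called in the opposite direction in any setting. Genes higher in GFP high numbered 1538; they numbered 2645 with the replicate block, 2397 with 1 surrogate variable, 737 at an adjusted p under 0.01 (lower, 1220), 175 against a fold change of 1.5 (lower, 251), 926 without both libraries numbered 3, and 1189 to 1479 with each library left out in turn. DESeq2 called 1873 higher and 2096 lower, and upper quartile scaling 1744 and 1760. The stricter thresholds lower counts by construction. Counts did not simply follow the number of libraries. Replicates 4 and 5 alone called 1332 higher and 1432 lower, more than the 926 and 1367 without both libraries numbered 3. The block removes the spread shared by pairs. It kept 3486 of 3511 calls and lowered the biological coefficient of variation from 0.249 to 0.1501. Lists past the test numbered 9 of 28; there were 16 of 33 without a low count filter, 15 with the replicate block, 2 with an estimated correlation (S phase, and G2 and mitosis) and 2 with that and the block (G2 and mitosis, and IL7R-STAT5 response; S phase adjusted p = 0.0906), and 9 to 11 with each library left out. Fry, which asks whether a list changed at all and not whether it differs from other genes, called 19. Pax5 (0.26, not past the threshold) passed with upper quartile scaling (0.30), the 10 CPM filter (0.29), the replicate block (0.26), 1 surrogate variable (0.27) and replicates 1 to 3 (0.31), and ranged from 0.24 to 0.34 with each library left out; over its alternatives adjusted p ran from 0.00352 to 0.148. Among the genes named by the rule and the list tests, the block changed the calls of Pax5, Kit, Myc, Cdkn1b, S100a9 and 6 lists, and none of these lists passed with the block and an estimated correlation. List tests within replicate sets or without a library used the preset correlation. Results not past the threshold that turned direction were the median of the Notch and T-lineage list (-0.07 without a low count filter, -0.09 to 0.42 with each library left out), Eln (0.37 in replicates 1 to 3, -0.63 in replicates 4 and 5, -0.23 to 0.084 with each library left out), Hdc (-0.042 in replicates 4 and 5, -0.062 to 0.51 with each left out), and the test directions of the plasma cell list (medians 0.22 with the replicate block and with that and an estimated correlation, 0.26 in replicates 1 to 3, 0.18 in replicates 4 and 5, 0.17 to 0.26 with each left out), the T cell list (0.76 in replicates 1 to 3; its median was -0.53 in replicates 4 and 5) and the erythroid list (0.39 in replicates 4 and 5). Apart from those named, the cause was not tested. Changes of 1.5-fold were recovered in 23.9% of simulated genes. That simulation used the spread of the unblocked fit and far fewer changed genes than were called in the data. It did not vary depth. Genes not past the threshold are not shown to be unchanged.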

Other observations

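Gene families were found by shared symbol stems among 10878 tested protein-coding genes, and their tests were chosen after the data were seen. Of 350 families with at least 5 tested genes, those of immune GTPases rose in GFP high: 6 of 8 Gimap genes and 6 of 8 Gbp genes were higher and 0 lower in each (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00408 for both). Gimap4, of a family linked to lymphocyte survival, had 551 ± 131 CPM in GFP high and 180 ± 90.5 CPM in GFP low (log2 fold change 1.62 ± 0.30), and Gimap6 had 701 ± 119 and 363 ± 55.8 CPM (0.95 ± 0.13). Gbp7, of the interferon-inducible guanylate-binding proteins, had 542 ± 103 and 270 ± 78.9 CPM (1.01 ± 0.19). Receptors of the TNF superfamily rose as well, with 7 of 12 Tnfrsf genes higher and 0 lower (adjusted p = 0.0082), among them Tnfrsf8 at 12.4 ± 1.82 against 2.66 ± 1.62 CPM. Of 26 genes with the stem Il, which holds interleukins and their receptors, 12 were higher and 2 lower (adjusted p = 0.0016), including Il10ra (1.65 ± 0.18) and Il6ra (1.45 ± 0.21) besides Il7r and Il2ra. Integrin alpha genes with the stem Itga followed by a number had 5 of 6 higher (adjusted p = 0.00667), and Itga6 fell (-1.59 ± 0.20). Those without a number in the symbol, such as Itgal, were not counted. Integrin beta genes, with the stem Itgb, had 2 higher and 4 lower of 7 and did not pass. The stem Cd, which holds unrelated genes and not only those of surface proteins, had 16 higher and 6 lower of 48 (adjusted p = 0.00707). From the calls with the replicate block the Itga family did not pass (adjusted p = 0.05897), whereas Gimap, Gbp, Tnfrsf, Il and Cd did. Apart from Il7r and Il2ra, all these genes were named after their values were seen. Genes of a family are not independent and can share reads, and the largest scaling shift, 0.04 on the log2 scale, is smaller than the median of each family.

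In all, 6 families passed for higher genes and 20 for lower genes. In the same Fisher's test on the calls with the replicate block, Lsm (adjusted p = 0.0703, unblocked 0.0121) and Cops (adjusted p = 0.121, unblocked 0.0352) no longer passed for lower genes. Clec (adjusted p = 0.0172, unblocked 0.236) and Irf (adjusted p = 0.0165, unblocked 0.495) passed for higher genes only with the block. Of 48 tested Mrpl genes, for large subunit proteins of the mitochondrial ribosome, 31 were lower and 1, Mrpl37, was higher (0.58 ± 0.07; adjusted p = 1.0e-10 for lower). All 13 tested Ndufa genes of respiratory complex I were lower (adjusted p = 1.83e-08), as were all 8 tested Psma genes of the proteasome (adjusted p = 7.89e-05) and the 6 genes found by the stem Cct, of a chaperonin that folds actin and tubulin (adjusted p = 0.00135). The folding stems Hspa (6 of 11 lower, adjusted p = 0.102) and Fkbp (6 of 10 lower, adjusted p = 0.0667) did not pass, nor did the ubiquitin ligase stem Rnf (12 higher and 2 lower of 60, adjusted p = 0.748 for higher, and with the replicate block 23 and 6, adjusted p = 0.06599). Psma5 fell by 0.62 ± 0.10 on the log2 scale and Cct8 by 0.55 ± 0.08. The 10 Mcm genes had 8 lower, which overlaps the S phase list. The cause of these shifts was not tested.

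Among the other summed immunoglobulin segments, heavy chain V segments stood at 1042 ± 108.5 CPM in GFP high and 900.2 ± 59.9 CPM in GFP low, higher in 5 of 5 pairs (two-sided exact permutation test, adjusted p = 0.0417, n = 5 each). Lambda constant genes (18.1 against 46.9 CPM, exact adjusted p = 0.222), lambda V segments (12.6 against 31.0 CPM, exact adjusted p = 0.222) and switched heavy chain constant genes (12.6 against 38.6 CPM, exact adjusted p = 0.437) did not pass. The lambda constant genes were lower in GFP high in pairs 1 to 3 and higher in pairs 4 and 5 (11.8 against 7.91 CPM and 17.4 against 9.38 CPM). The mean of the switched heavy chain genes in GFP low came from libraries 3 and 5 (84.8 and 92.2 CPM), against 3.25 to 7.04 CPM in the other GFP low libraries and 5.66 to 16.8 CPM in GFP high, and they were higher in GFP high in 3 of 5 pairs. Igkc summed to 290 ± 80.5 CPM in GFP high and 857 ± 219 CPM in GFP low (exact adjusted p = 0.0185). None of these exact tests kept the pairs together.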
